A study of Homo sapiens with 26 samples.

How the data were processed

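Per the labels' protocols, MDA-MB-231 cells (estrogen receptor negative) and T47D cells (estrogen receptor positive) were grown in hydrogels of a 4-arm poly(ethylene glycol) joined by a crosslinker that cells can degrade. The gels carried the peptide GFOGER, a mimic of collagen, or IKVAV, a mimic of laminin. A gel named 10 wt% with GFOGER was set against the gel without that name, called standard here, and the labels give no measured stiffness. Gels were dissolved with collagenase, 3 gels were pooled for each RNA replicate, the RNA was treated with DNase, and libraries were made with a kit that selects mRNA. Nothing in the labels says that replicates came from separate cultures, so spread between them may lie below that between cultures.

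The 26 libraries form 10 groups, 5 per line. Titles name D3 or D40, while the field for the day and the text on design give day 3 for every sample. The titles were followed, since the sample descriptions and the column names of the count table name the same day as the title in all 26, and the doubt raised by that field remains. Replicate numbers in titles run from 1 to 3, except 4 for the single D3 IKVAV libraries, and the description of that of MDA-MB-231 names 5.

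The authors deposited raw counts, whole numbers of reads per gene and library that are not normalised, in a table of 24656 gene entries and 26 columns, all of which were used. Per the submitters' processing notes, the tools were FastQC, Trim Galore 0.4.4, TopHat2 2.1.0, bedtools 2.17, SAMtools 1.4, HTSeq 0.6.1p1 and edgeR 3.16.5 with genome hg19. What each tool did, the strand counted, the annotation release and the handling of reads that fit several places are not given in the sources used here. Genes that overlap another on the opposite strand and genes with near-identical copies are therefore uncertain. Coordinates are those of the table, and gene kinds came from GENCODE v29 by name. Of the entries, 1588 share a symbol with another and were kept apart by position, 1258 on haplotype or unplaced sequences hold 0 counts, 28 symbols had been turned into dates, and 3418 have no count.

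Counts were fitted with edgeR 4.0.16 in R 4.3.3 by negative binomial models with quasi-likelihood F tests. TMM factors scaled the libraries and filterByExpr chose the genes (15630 in MDA-MB-231, 15836 in T47D, 16971 in a fit of both lines). Each line was fitted on its 13 libraries, with 8 residual degrees of freedom and a common coefficient of biological variation of 0.125 (MDA-MB-231) and 0.096 (T47D). Differences between lines came from 1 fit of all libraries (16 degrees of freedom, 0.111). Within each line 4 comparisons were tested: D40 with D3 in the 10 wt% GFOGER gel, 10 wt% with standard GFOGER at D40, IKVAV with GFOGER at D40, and D40 with D3 in IKVAV. The last has 1 D3 library per line and borrows its variance from the other groups. For the first 3, the T47D change minus the MDA-MB-231 change was tested as well, as was T47D with MDA-MB-231 at D40. P-values were adjusted by Benjamini and Hochberg within each comparison, and an adjusted p under 0.05 was called changed. Standard errors are the log2 fold change over the root of F. For a group at 0, the fold is a lower bound that sets that group at 3 counts per library.

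Before the data were examined, 34 lists of genes were fixed from general knowledge, and 33 could be tested with at least 5 members. None of the 13 genes of the mitochondrial list is in the table, so that list has no result. Lists were tested with camera of limma 3.58.1 on voom weights at its preset correlation of 0.01, and again with the correlation estimated from the data, each adjusted over the lists of a comparison. Members were also counted with p adjusted over the list alone.

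Genes were named by a rule. In each main comparison these were the 4 largest increases and 4 largest decreases among genes that changed at least 2-fold, had a mean of at least 5 CPM in the higher group and did not overlap between groups, without uncharacterised and small RNA genes. Added to these were the 2 members with the smallest p in the direction of each of up to 8 lists, and genes chosen beforehand for each question. CPM in the text are per total count without the TMM factor, which was 0.778 to 0.812 in MDA-MB-231 at D40 in the 10 wt% gel and 1.06 to 1.08 at D3, so there a fold is not the ratio of CPM.

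The code was tested on simulated data with known changes. Per comparison, 66 or 67 genes changed at each of 1.5-fold, 2-fold and 4-fold, up or down, and all others stayed equal. In the real main comparisons up to 11167 of 15630 genes changed, so the simulated rates do not cover scaling under such wide change. Of genes changed 2-fold, 85.1 to 92.5% were found in the main comparisons, and of genes changed 4-fold 95.5 to 100%. Between lines, 4-fold changes were found in 89.4, 83.3 and 92.4% of cases for time, gel and peptide. Data simulated without change gave 0 to 2 calls. A limit set for this test, that every comparison find more than 90% of 4-fold changes, was missed by 2 of the between-line tests. Most genes missed had under 1 CPM, and the limit was then changed to genes above 1 CPM, after the outcome was seen.

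Alternatives set before the data were examined were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom, no filter, a stricter filter (5 CPM in 3 libraries), robust dispersion, only the libraries compared, the replicate number as a block, a 2-fold minimum, each library left out, and for lists an estimated correlation and fry. Added after seeing the data were fits without pseudogenes and genes with copies, a fit without the 10 most abundant genes of each library, and lists without 2 divergent libraries. Left out were imaging, stiffness and growth measurements, which were not analysed here, and alignment from reads, since only counts were used.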

Results

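RNA was sequenced from MDA-MB-231 and T47D breast cancer cells held in synthetic gels that carried a collagen-mimicking peptide (GFOGER) or a laminin-mimicking peptide (IKVAV). Each line gave 13 libraries: 3 each from the 10 wt% GFOGER gel at D3 and at D40, 3 each from the standard GFOGER and IKVAV gels at D40, and 1 from the standard IKVAV gel at D3. Sequencing depth ran from 13326874 to 21987257 counted reads per library. Levels are in counts-per-million (CPM), and folds come from the edgeR fit, which also scales for the make-up of each library.

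The 2 lines kept their known identities. ESR1, the estrogen receptor (hg19 chromosome 6, 152011631 to 152424408), was higher in T47D than in MDA-MB-231 across the D40 groups (log2 fold change 8.66, SE 0.12, edgeR adjusted p = 3.34e-30). Group means of ESR1 were 190.2 to 232.6 CPM in T47D and 0.177 to 0.402 CPM in MDA-MB-231. PGR, the progesterone receptor, and the luminal factor GATA3 were also higher in T47D (log2 8.71 and 6.45), as was the adhesion gene CDH1 (log2 8.05). The mesenchymal filament gene VIM and the caveolar gene CAV1 were lower in T47D (log2 -8.88 and -8.48), as were the receptor kinase AXL and the hyaluronan receptor CD44 (log2 -7.23 and -3.32). At D40, 14431 of 16971 genes differed between the lines, 7380 higher and 7051 lower in T47D. Of 18 blood and stromal cell markers, 7 could be tested in each line, and over time in the 10 wt% gel of MDA-MB-231 they were mixed (3 rose, 3 fell, 1 did not pass, median log2 0.21, camera adjusted p = 0.774, adjusted p = 0.777 with an estimated correlation).

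The libraries fell into 2 sets that did not follow the line. EEF1A1, a translation factor with many pseudogene copies, stood at 361.5 to 627.4 CPM in the 12 standard-gel D40 libraries and at 7902 to 23570 CPM in the other 14. MTRNR2L2, a nuclear gene resembling mitochondrial ribosomal RNA, stood at 1.28 to 21.0 CPM in the first set and 1468 to 6936 CPM in the second. Ribosomal protein genes took 0.827 to 1.54% of counts in the first set and 1.78 to 2.73% in the second. The D3 IKVAV libraries, though from a standard gel, belong to the second set. The comparison of 10 wt% with standard gel, and that of D40 with D3 in IKVAV, therefore run between the sets, while time in the 10 wt% gel and the peptide comparison run within a set, though levels inside the second set also differ in MDA-MB-231.

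**Figure D1:**
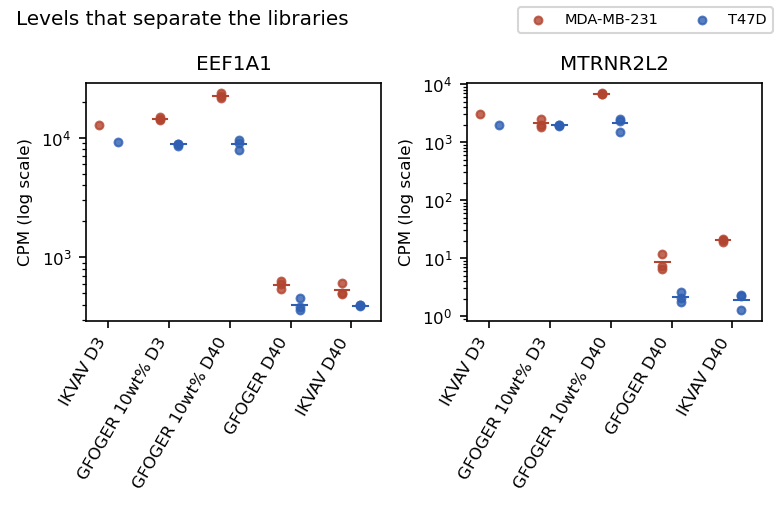
EEF1A1 and MTRNR2L2 in CPM, log scale, for each library of both lines. Dots are libraries and short lines are group means.

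In MDA-MB-231 cells in the 10 wt% GFOGER gel, genes of DNA replication and mitosis were lower at D40 than at D3, and genes of protein folding in the endoplasmic reticulum (ER) were higher. MKI67, a marker of cycling cells (hg19 chromosome 10, 129894925 to 129924468), stood at 69.8 ± 13.3 CPM at D40 and 899.8 ± 57.2 CPM at D3 (SD, n = 3 each). The fit put it 9.60-fold lower (log2 fold change -3.26, SE 0.12, edgeR adjusted p = 1.90e-13). HSPA5, the main ER chaperone (chromosome 9, 127997127 to 128003666), rose from 806.1 ± 46.1 to 9584 ± 872.1 CPM, or 16.0-fold (log2 4.00, SE 0.13, edgeR adjusted p = 5.06e-14, n = 3 each). IL1B, an inflammatory cytokine (chromosome 2, 113587337 to 113594356), rose from 1.63 ± 0.272 to 242.6 ± 11.7 CPM, or 201-fold (log2 7.65, SE 0.37). VEGFA, an angiogenic factor induced by low oxygen (chromosome 6, 43737946 to 43754223), rose 10.5-fold from 375.7 ± 17 to 2945 ± 114.7 CPM (log2 3.4, SE 0.17).

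Of 40 proliferation genes in MDA-MB-231, 39 fell over this time and 1 did not pass (median log2 -2.64, camera adjusted p = 1.30e-17, adjusted p = 0.176 with an estimated correlation). MCM3, part of the replicative helicase, fell from 323.4 ± 6.28 to 30.4 ± 2.63 CPM, and the topoisomerase TOP2A from 753.7 ± 97.9 to 203.3 ± 30.9 CPM (log2 -2.98 and -1.47). Of 18 cell cycle exit genes, 14 rose and 3 fell (median log2 1.28, camera adjusted p = 0.00448, adjusted p = 0.574 with an estimated correlation). The cyclin-dependent kinase inhibitor CDKN1A rose 4.68-fold to 365.5 ± 10.8 CPM. CDKN1B, a second such inhibitor, rose 1.4-fold (log2 0.49, SE 0.12, edgeR adjusted p = 0.00103) with overlapping levels of 63.4 ± 5.40 and 60.8 ± 5.72 CPM (n = 3). NR2F1, a dormancy-associated receptor, did not change (log2 0.22, SE 0.12, edgeR adjusted p = 0.129).

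ER chaperones rose in 19 of 20 cases (median log2 1.59, camera adjusted p = 1.00e-09, adjusted p = 0.187 with an estimated correlation), among them HSP90B1, which rose 8.72-fold to 5187 ± 164.1 CPM. Immediate early genes, a group that cell dissociation can also induce, rose in 21 of 25 cases and fell in 2 (median log2 1.67, camera adjusted p = 9.09e-07, adjusted p = 0.261 with an estimated correlation). EGR1, an early growth factor target, rose 15.6-fold and the AP-1 subunit JUNB 7.08-fold. Interferon response genes went the other way: 27 of 34 fell and 6 rose (median log2 -1.97, camera adjusted p = 3.56e-06, adjusted p = 0.176 with an estimated correlation). IFIT3, an antiviral effector (chromosome 10, 91087602 to 91100725), was 15.4-fold lower, at 12.1 ± 1.13 against 250.4 ± 24.9 CPM, and the RNA sensor DDX58 14.1-fold lower. Of 28 hypoxia genes, 20 rose and 3 fell (median log2 1.61, camera adjusted p = 0.000398, adjusted p = 0.679 with an estimated correlation). The prolyl hydroxylase gene P4HA1 rose 6.58-fold, and CA9, a carbonic anhydrase induced by hypoxia, had 517 counts at D40 and 9 at D3.

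Ribosomal protein genes rose in 31 of 32 cases (median log2 0.86, camera adjusted p = 1.00e-09, adjusted p = 0.368 with an estimated correlation). RPL22 and RPS16 rose 2.59-fold and 2.44-fold, though both have pseudogene copies and their counts are uncertain. Of 30 inflammatory cytokine and NF-kB genes, 20 rose and 3 fell (median log2 1.16, camera adjusted p = 0.00276, adjusted p = 0.574 with an estimated correlation). The iron-binding protein LCN2 rose from 1.25 ± 0.459 to 185.4 ± 70.1 CPM and the cytokine LIF 6.51-fold. Heat shock genes rose in 10 of 15 cases (median log2 0.53, camera adjusted p = 0.00123, adjusted p = 0.574 with an estimated correlation), with HSPA1B and HSPA1A, near-identical copies, at log2 3.23 and 2.47. A median this small depends on the scaling. Totals in place of TMM lowered that of 18 ER chaperones from 1.44 to 1.01 in this comparison, and scaling acts on all genes alike. Basement membrane genes rose in 13 of 21 cases and fell in 2 (median log2 0.77, camera adjusted p = 0.0164, adjusted p = 0.347 with an estimated correlation). Matrix proteases and crosslinkers rose in 19 of 33 cases and fell in 8 (median log2 0.94, camera adjusted p = 0.0164, adjusted p = 0.176 with an estimated correlation). The collagenase MMP1 rose from 30.8 ± 3.87 to 2360 ± 188.7 CPM. Among the lists above, only the count of immediate early genes differed when p was adjusted over the list alone (22 risen and 2 fallen).

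The largest increases over this time in MDA-MB-231, besides IL1B, were the innate receptor TREM1 (1172 counts at D40 and 1 at D3), the keratin KRT4 (6.46 ± 0.888 CPM against 0, at least 41.2-fold) and the muscle protein IGFN1 (17.5 ± 2.09 CPM against 2 counts). The largest decreases were the angiopoietin ANGPT1 (2 counts against 325), the epidermal protein FLG (85.1-fold lower), the interferon-induced SAMD9L (chromosome 7, 92759368 to 92777680, 82.6-fold lower) and the replication factor FAM111B (55.3-fold lower). In all, 11167 of 15630 genes changed, 5561 up and 5606 down, of which 3134 rose and 3479 fell at least 2-fold. The 10 most abundant genes took 7.61 to 8.01% of counts at D40 and 4.45 to 4.88% at D3. MTRNR2L2, which marks the library sets, shifted as well, at 6817 ± 155.8 against 2105 ± 351.7 CPM. The nuclear RNA MALAT1, whose levels overlap between the sets, stood at 3055 ± 145.8 against 882.2 ± 241.2 CPM. The cause of these shifts was not tested. In data simulated on these libraries with few genes changed, the fit recovered 57 of 67 genes changed 2-fold, and 5.9% of its calls were false.

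**Figure D2:**
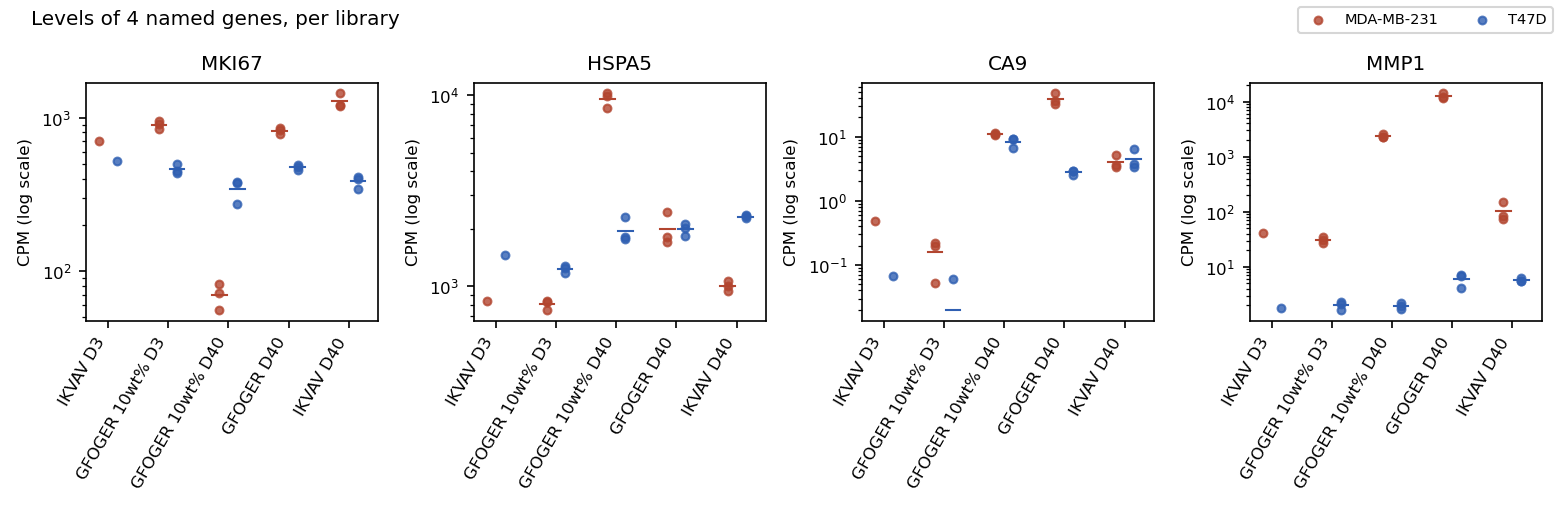
MKI67, HSPA5, CA9 and MMP1 in CPM, log scale, for each library by line and group. Short lines are group means, and 2 T47D libraries of the 10 wt% gel at D3 with no CA9 count are not drawn.

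In T47D cells in the same 10 wt% gel, hypoxia genes were higher at D40 than at D3, while genes of cholesterol synthesis, oxidative phosphorylation and proliferation were lower. NDRG1, a stress gene induced by low oxygen (hg19 chromosome 8, 134249414 to 134309547), rose from 6.19 ± 0.734 to 481.1 ± 121.5 CPM (SD, n = 3 each), or 75.2-fold (log2 6.23, SE 0.25, edgeR adjusted p = 8.43e-12). PDK1, a kinase that restrains pyruvate dehydrogenase (chromosome 2, 173420779 to 173463862), rose 12.8-fold from 8.46 ± 0.941 to 110.9 ± 10.0 CPM (log2 3.67, SE 0.14). FDFT1, the squalene synthase (chromosome 8, 11660190 to 11696818), was 3.59-fold lower at 96.9 ± 4.09 against 336.6 ± 16.8 CPM (log2 -1.84, SE 0.09). MKI67 fell by far less than in MDA-MB-231 (log2 -0.47, SE 0.11, edgeR adjusted p = 0.00212), to 340.3 ± 59.7 from 458.3 ± 32.5 CPM (n = 3 each).

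Of 28 hypoxia genes in T47D, 27 rose over this time and 1 did not pass (median log2 2.16, camera adjusted p = 3.13e-18, adjusted p = 0.0628 with an estimated correlation). VEGFA rose to 428.2 ± 305.3 from 34.3 ± 1.95 CPM (log2 3.58, SE 0.32), CA9 had 380 counts at D40 and 1 at D3, and the mitophagy gene BNIP3, which has pseudogene copies, rose by log2 3.30. All 24 cholesterol synthesis genes fell (median log2 -1.35, camera adjusted p = 2.72e-17, adjusted p = 0.0628 with an estimated correlation), with DHCR7, which makes the final step, at log2 -1.39. Of 40 oxidative phosphorylation genes, 39 fell (median log2 -0.72, camera adjusted p = 1.25e-16, adjusted p = 0.288 with an estimated correlation), among them the complex I genes NDUFA2 and NDUFB10 (log2 -1.09 and -0.81). Of 40 proliferation genes, 38 fell (median log2 -0.92, camera adjusted p = 3.87e-16, adjusted p = 0.318 with an estimated correlation), such as the mitotic activator CDC20 and the ubiquitin enzyme UBE2C (log2 -1.51 and -1.33). CDKN1A rose by log2 0.30 (SE 0.09, edgeR adjusted p = 0.0121, n = 3 each) and CDKN1B did not change (log2 -0.11).

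Heat shock genes of T47D fell in 12 of 15 cases (median log2 -0.65, camera adjusted p = 3.44e-05, adjusted p = 0.155 with an estimated correlation), among them HSPH1 at log2 -1.37. Glycolysis genes rose in 11 of 15 cases and fell in 3 (median log2 1.08, camera adjusted p = 7.81e-05, adjusted p = 0.225 with an estimated correlation), with the phosphofructokinase PFKP at 430.4 ± 16.4 against 79.1 ± 2.88 CPM. Fatty acid synthesis and storage genes fell in 12 of 20 cases and rose in 1 (median log2 -0.32, camera adjusted p = 0.00100, adjusted p = 0.0628 with an estimated correlation), among them the carboxylase ACACA and the citrate lyase ACLY (log2 -1.38 and -1.25). Dormancy-associated genes rose in 15 of 25 cases and fell in 3 (median log2 0.78, camera adjusted p = 0.00485, adjusted p = 0.0628 with an estimated correlation). The receptor TGFBR3 rose by log2 1.67 while NR2F1 fell by log2 1.5, from 1.10 to 0.399 CPM. ATF4 stress genes rose in 15 of 23 cases and fell in 4 (median log2 0.68, camera adjusted p = 0.00606, adjusted p = 0.318 with an estimated correlation). Estrogen response genes rose in 17 of 30 cases and fell in 2 (median log2 0.40, camera adjusted p = 0.00686, adjusted p = 0.503 with an estimated correlation).

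Interferon response genes of T47D rose in 17 of 34 cases and fell in 1 (median log2 0.79, camera adjusted p = 0.00626, adjusted p = 0.568 with an estimated correlation). Matrix proteases and crosslinkers rose in 11 of 26 cases (median log2 0.43, camera adjusted p = 0.00606, adjusted p = 0.235 with an estimated correlation). Basement membrane genes rose in 9 of 19 cases and fell in 1 (median log2 0.68, camera adjusted p = 0.00626, adjusted p = 0.155 with an estimated correlation), and interstitial matrix genes rose in 10 of 21 and fell in 1 (median log2 0.70, camera adjusted p = 0.00686, adjusted p = 0.235 with an estimated correlation). Lysosome and autophagy genes fell in 14 of 25 cases and rose in 5 (median log2 -0.30, camera adjusted p = 0.00686, adjusted p = 0.436 with an estimated correlation), and replication-dependent histones fell in 6 of 13 (median log2 -0.93, camera adjusted p = 0.0156, adjusted p = 0.471 with an estimated correlation). Immediate early genes rose in 13 of 25 cases and fell in 2 (median log2 0.66, camera adjusted p = 0.0242, adjusted p = 0.503 with an estimated correlation), and inflammatory genes rose in 10 of 25 and fell in 1 (median log2 0.65, camera adjusted p = 0.0485, adjusted p = 0.568 with an estimated correlation). Single D40 libraries moved 5 of these medians in T47D: histones to -1.44, immediate early genes to 0.35 and inflammatory genes to 0.41 without library 3, interferon response to 0.40 (12 risen) without library 2, and fatty acid synthesis to -0.51 without library 1. Adjusted over the list alone, the counts became 2 risen and 13 fallen for fatty acid synthesis, 15 and 4 for dormancy, 16 and 4 for ATF4 stress, 14 and 2 for immediate early genes and 17 and 3 for estrogen response, and the other counts of these paragraphs on T47D stayed.

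The largest increases over this time in T47D, besides NDRG1 and CA9, were the transcription factor ZBTB16 (5.43 ± 1.80 CPM against 0, at least 29.4-fold) and the scaffold gene PPFIA4 (chromosome 1, 203020311 to 203047864, log2 6.18). The largest decreases were smaller: the prostaglandin dehydrogenase HPGD (log2 -2.76), OTOR (log2 -2.75), the lipoprotein receptor OLR1 (log2 -2.53) and ZNF488 (log2 -2.50). In all, 8348 of 15836 genes changed, 4096 up and 4252 down, of which 1614 rose and 481 fell at least 2-fold. The third D40 library differed from the other 2 in the nuclear RNA MALAT1 (18040 against 4264 and 4059 CPM). It also differed more widely: the chi-square per degree of freedom of counts between 2 replicates was 34.49 and 33.93 with it and 4.92 without it. Without this library 8167 genes changed and 26 hypoxia genes rose. List medians went from 2.16 to 1.98 for hypoxia, -0.92 to -0.74 for proliferation, -0.72 to -0.61 for oxidative phosphorylation and 1.08 to 1.2 for glycolysis. In data simulated on these libraries with few genes changed, the fit recovered 59 of 67 genes changed 2-fold, and 5.7% of its calls were false.

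The change over time differed between the lines for 9416 of 16971 genes, with 5265 differences above 0 and 4151 below (T47D minus MDA-MB-231). Of 33 lists, 13 passed with camera and 0 with an estimated correlation. ER chaperones, which rose in MDA-MB-231, had 19 of 20 differences below 0 (median log2 -1.27, camera adjusted p = 2.01e-12, adjusted p = 0.0633 with an estimated correlation). Proliferation genes had 34 of 40 above 0 (median log2 1.55, camera adjusted p = 6.64e-11, adjusted p = 0.458 with an estimated correlation), so the fall in MDA-MB-231 was the larger one. Interferon response genes moved in opposite directions in the lines, and 29 of 34 differences were above 0 (median log2 3.14, camera adjusted p = 4.98e-07, adjusted p = 0.461 with an estimated correlation). Across 14486 genes the log2 fold changes of the lines correlated at 0.280 (Pearson) and 0.302 (Spearman). None of these list counts changed when adjusted over the list alone. Of 5864 genes that changed in both lines, 4070 (69.4%) moved the same way.

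In MDA-MB-231 cells at D40, the 10 wt% GFOGER gel differed from the standard GFOGER gel in lower proliferation genes and matrix proteases and in higher ribosomal, chaperone and cholesterol synthesis genes. These libraries lie in different sets, so gel and set cannot be told apart. Ribosomal protein genes themselves mark the sets. They took 1.78% of counts in the D3 IKVAV library, a standard gel of the second set that also differs in peptide and time. In standard GFOGER at D40 they took 0.845 to 0.888%, and in the 10 wt% gel at D40 2.6 to 2.66%. MKI67 stood at 69.8 ± 13.3 CPM in the 10 wt% gel and 821.6 ± 40.9 CPM in the standard gel (SD, n = 3 each), 9.22-fold lower (log2 fold change -3.21, SE 0.12, edgeR adjusted p = 1.17e-13). CTGF, a target of YAP signalling (hg19 chromosome 6, 132269317 to 132272518), was 9.29-fold lower at 60.5 ± 5.27 against 715.7 ± 190.4 CPM (log2 -3.22, SE 0.16). HSPA5 was 6.16-fold higher (log2 2.62, SE 0.12), at 9584 ± 872.1 against 1993 ± 397.5 CPM. MSMO1, a sterol oxidase (chromosome 4, 166248818 to 166264314), was 13.6-fold higher at 295.6 ± 43.6 against 28 ± 7.63 CPM (log2 3.76, SE 0.17).

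Of 40 proliferation genes in MDA-MB-231, 36 were lower in the 10 wt% gel (median log2 -1.48, camera adjusted p = 1.32e-11, adjusted p = 0.175 with an estimated correlation), among them the transcription factor MYBL2 at 5.44 against 64.7 CPM. All 32 ribosomal protein genes were higher (median log2 1.91, camera adjusted p = 4.54e-20, adjusted p = 0.175 with an estimated correlation), with RPL7A at 1392 ± 21.2 against 121.6 ± 4.74 CPM and RPL32 at log2 2.98, genes with copies whose counts are uncertain. Oxidative phosphorylation genes were higher in 31 of 40 cases and lower in 1 (median log2 0.64, camera adjusted p = 3.63e-07, adjusted p = 0.289 with an estimated correlation), such as SDHD of complex II at log2 2.20. The lists of this comparison were not tested again without genes with copies, so members with copies may add to these shifts. ER chaperones were higher in 16 of 20 cases (median log2 0.71, camera adjusted p = 3.70e-06, adjusted p = 0.257 with an estimated correlation), including the disulfide isomerase PDIA3 at log2 1.91. Heat shock genes were higher in 13 of 15 cases and lower in 1 (median log2 1.11, camera adjusted p = 2.66e-05, adjusted p = 0.283 with an estimated correlation), with the cochaperone CHORDC1 at log2 3.48. Cholesterol synthesis genes were higher in 17 of 25 cases and lower in 5 (median log2 1.51, camera adjusted p = 4.20e-05, adjusted p = 0.212 with an estimated correlation), with HMGCS1 at 140.9 ± 5.86 against 35.7 ± 1.18 CPM.

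Matrix proteases and crosslinkers of MDA-MB-231 were lower in 21 of 33 cases and higher in 3 (median log2 -0.86, camera adjusted p = 0.00194, adjusted p = 0.132 with an estimated correlation). The gelatinase MMP9 (chromosome 20, 44637547 to 44645200) was 27.3-fold lower, at 0.915 ± 0.340 against 32.1 ± 5.42 CPM, and ADAMTS1 10.8-fold lower. YAP and TEAD targets were lower in 19 of 24 cases and higher in 5 (median log2 -0.84, camera adjusted p = 0.00316, adjusted p = 0.434 with an estimated correlation). ANKRD1, a target responsive to cell tension, was 5.39-fold lower, while CYR61 was 1.28-fold higher in the fit (log2 0.36, SE 0.14, edgeR adjusted p = 0.0296, n = 3) at overlapping levels of 2069 ± 182 and 2049 ± 484 CPM. The CYR61 call was lost with only the libraries compared (edgeR adjusted p = 0.0668), without standard gel library 1 or 2 (0.128 and 0.123) and without 10 wt% gel library 1 or 3 (0.0592 and 0.106). Interstitial matrix genes were lower in 17 of 24 cases and higher in 2 (median log2 -1.23, camera adjusted p = 0.00375, adjusted p = 0.257 with an estimated correlation). Inflammatory genes were lower in 18 of 30 cases and higher in 2 (median log2 -0.98, camera adjusted p = 0.00194, adjusted p = 0.511 with an estimated correlation), and interferon response genes lower in 20 of 34 and higher in 5 (median log2 -1.10, camera adjusted p = 0.00208, adjusted p = 0.257 with an estimated correlation). MDA-MB-231 line markers, among them CAV1 (log2 -1.69), were lower in 16 of 20 cases and higher in 2 (median log2 -0.79, camera adjusted p = 0.00112, adjusted p = 0.175 with an estimated correlation). The collagen receptor ITGA2 (log2 -1.38), the collagen crosslinker LOX (log2 -1.11) and CA9 (log2 -1.44) were lower too. ER chaperones that were higher numbered 17 when adjusted over the list alone, and no other count of this comparison changed.

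The genes furthest apart between the gels in MDA-MB-231 were mostly pseudogenes or genes with copies. ESRG (35.6 ± 7.04 CPM, at least 245-fold), WASH5P (27.5 ± 0.187 CPM, at least 189-fold) and TMEM212 (22.5 ± 4.53 CPM, at least 154-fold) had 0 counts in the standard gel, and MTRNR2L10 was higher by log2 11.08. The histone gene H3F3C (40.2 ± 4.15 CPM, at least 209-fold lower), UBE2MP1 (at least 125-fold lower), RNF5P1 (at least 88.8-fold lower) and CRSP8P (at least 57.8-fold lower) had 0 counts in the 10 wt% gel. In all, 11016 of 15630 genes differed, 5264 higher and 5752 lower in the 10 wt% gel, of which 2478 and 3384 differed at least 2-fold. In data simulated on these libraries with few genes changed, the fit recovered 60 of 67 genes changed 2-fold, and 8% of its calls were false.

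In T47D cells at D40, the 10 wt% GFOGER gel gave higher hypoxia and glycolysis genes and lower inflammatory and interferon genes than the standard GFOGER gel, again with gel and library set inseparable. ERO1L, an oxidase of protein folding induced by low oxygen (hg19 chromosome 14, 53108605 to 53162419), stood at 526.6 ± 72.5 CPM in the 10 wt% gel and 199.2 ± 25.3 CPM in the standard gel (SD, n = 3 each), 2.72-fold higher (log2 1.45, SE 0.09). SAA1, an acute-phase protein (chromosome 11, 18287808 to 18291523), was 7.57-fold lower at 2.28 ± 1.22 against 17.6 ± 1.09 CPM (log2 -2.92, SE 0.33), though SAA2 (log2 -2.54) is nearly identical to it. IFIT2, an interferon target (chromosome 10, 91061706 to 91069033), was 5.38-fold lower at 7.11 ± 2.45 against 39.4 ± 10.7 CPM (log2 -2.43, SE 0.24). CA9 was 3.11-fold higher (log2 1.64, SE 0.25, edgeR adjusted p = 4.78e-05), at 8.37 against 2.79 CPM.

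Of 28 hypoxia genes in T47D, 27 were higher in the 10 wt% gel (median log2 1.37, camera adjusted p = 1.06e-16, adjusted p = 0.280 with an estimated correlation), with BNIP3 at log2 2.54. Glycolysis genes were higher in 10 of 15 cases (median log2 0.91, camera adjusted p = 5.59e-06, adjusted p = 0.382 with an estimated correlation), with the isomerase TPI1 at 286.5 against 86.0 CPM and PGAM1, which has copies, at log2 4.65. Here too the lists were not tested again without genes with copies. Ribosomal protein genes were higher in 27 of 32 cases (median log2 0.85, camera adjusted p = 7.96e-18, adjusted p = 0.382 with an estimated correlation), with RPL7A at 1906 ± 119 against 285.5 ± 17.3 CPM. These genes mark the sets: they took 2.58% of counts in the D3 IKVAV library, a standard gel of the second set. In standard GFOGER at D40 they took 1.36 to 1.5%. Oxidative phosphorylation genes were higher in 17 of 40 cases and lower in 2 (median log2 0.16, camera adjusted p = 0.00128, adjusted p = 0.951 with an estimated correlation). Inflammatory genes were lower in 20 of 25 cases and higher in 1 (median log2 -1.18, camera adjusted p = 3.83e-06, adjusted p = 0.684 with an estimated correlation). Interferon response genes were lower in 22 of 34 cases and higher in 1 (median log2 -0.77, camera adjusted p = 6.27e-06, adjusted p = 0.951 with an estimated correlation), among them SAMD9 at log2 -1.65. Antigen presentation genes were lower in 12 of 18 cases (median log2 -0.38, camera adjusted p = 0.000359, adjusted p = 0.9 with an estimated correlation), with the class II chaperone CD74 at 110.0 ± 39.7 against 384.8 ± 38.8 CPM. YAP and TEAD targets were lower in 13 of 22 cases and higher in 4 (median log2 -0.45, camera adjusted p = 0.0114, adjusted p = 0.382 with an estimated correlation). The Hippo pathway gene FJX1 was at log2 -1.76, CYR61 at -0.87 and CTGF at -1.34 with 1.11 against 2.92 CPM.

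Single 10 wt% gel libraries moved 3 of these medians in T47D: inflammatory genes to -1.92 without library 3, interferon response to -1.23 without library 2, and oxidative phosphorylation to 0.09 without library 1 and 0.26 without library 3. Proliferation genes did not pass between these gels (1 higher and 8 lower of 40, median log2 -0.12, camera adjusted p = 0.228, adjusted p = 0.951 with an estimated correlation). Adjusted over the list alone, the counts higher and lower became 28 and 0 for hypoxia, 1 and 22 for inflammatory genes, 0 and 13 for antigen presentation, 18 and 2 for oxidative phosphorylation and 0 and 7 for proliferation, and the others stayed. LOX was higher (log2 0.88, edgeR adjusted p = 0.00283, n = 3), while ANKRD1 (log2 -0.01) and ITGA2 (log2 0.12) did not change. The genes furthest apart again included pseudogenes and genes with copies. BCYRN1 (53.7 ± 9.61 CPM, at least 342-fold), SMA4 (at least 168-fold) and WASH5P (at least 140-fold) had 0 counts in the standard gel, and SPDYE7P had 1. CRSP8P (at least 67.8-fold lower), RACGAP1P (at least 52.0-fold lower) and CSDAP1 (at least 45.7-fold lower) had 0 counts in the 10 wt% gel, and NACA2 was at log2 -10.72. In all, 6778 of 15836 genes differed, 3362 higher and 3416 lower, of which 1376 and 506 at least 2-fold. In data simulated on these libraries with few genes changed, the fit recovered 62 of 67 genes changed 2-fold, and 4.4% of its calls were false.

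The difference between the gels itself differed between the lines for 8728 genes, 5292 with T47D minus MDA-MB-231 above 0 and 3436 below. This split was not stable: it was 3977 and 3888 with only the libraries compared and 4856 and 3879 with DESeq2 size factors. With camera 9 of 33 lists passed, and with an estimated correlation 0 did. Proliferation genes had 37 of 40 differences above 0 (median log2 1.4, camera adjusted p = 2.32e-11, adjusted p = 0.304 with an estimated correlation), and hypoxia genes 26 of 28 (median log2 1.84, camera adjusted p = 1.99e-10, adjusted p = 0.233 with an estimated correlation). ER chaperones had 17 of 20 below 0 (median log2 -0.65, camera adjusted p = 5.55e-10, adjusted p = 0.111 with an estimated correlation), and cholesterol synthesis genes 17 of 25 below and 3 above (median log2 -1.10, camera adjusted p = 5.56e-08, adjusted p = 0.111 with an estimated correlation). ER chaperones and cholesterol genes below 0 numbered 18 each when adjusted over the list alone, and the other counts stayed. The log2 fold changes of the lines correlated at 0.653 (Pearson) and 0.336 (Spearman) across 14486 genes. Of 4777 genes that differed in both lines, 3415 (71.5%) went the same way. In both lines this comparison runs between the same library sets. A shift shared by the sets can therefore raise this correlation and the share of genes that went the same way. Without pseudogenes and genes with copies the Pearson correlation was 0.614.

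**Figure D3:**
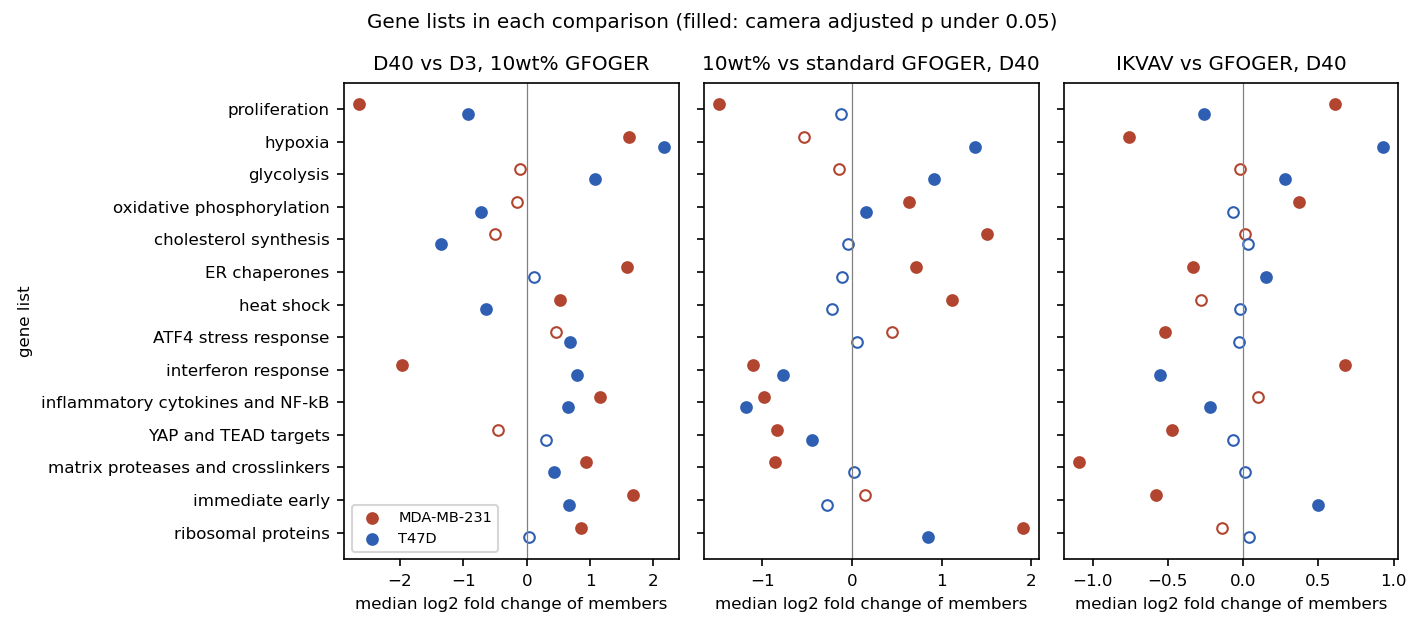
Medians of the log2 fold changes in 14 gene lists for time in the 10 wt% gel, gel at D40 and peptide at D40, by line. Filled points passed a camera adjusted p under 0.05.

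In MDA-MB-231 cells at D40, the IKVAV gel gave lower matrix proteases and hypoxia genes and higher proliferation and interferon genes than the GFOGER gel of the same kind. MMP1, the interstitial collagenase (hg19 chromosome 11, 102660641 to 102668966), stood at 101.9 ± 42.4 CPM with IKVAV and 12510 ± 1404 CPM with GFOGER (SD, n = 3 each), 133-fold lower (log2 fold change -7.06, SE 0.24, edgeR adjusted p = 5.86e-13). IQGAP2, a scaffold of the cytoskeleton (chromosome 5, 75699149 to 76003957), rose from 2.24 ± 0.522 to 163.0 ± 36.4 CPM (log2 6.05, SE 0.28). MUC5B, a gel-forming mucin (chromosome 11, 1244295 to 1283406), was 38.8-fold higher at 2816 ± 113 against 66.7 ± 35.5 CPM (log2 5.28, SE 0.39). CA9 was 10.3-fold lower, at 4.03 ± 0.956 against 38.4 ± 7.82 CPM (log2 -3.37, SE 0.19). ITGA2, the receptor subunit that binds collagen, was also lower at 539.9 ± 18.2 against 1223 ± 217 CPM (log2 -1.29, SE 0.12, edgeR adjusted p = 1.24e-07, n = 3 each).

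Of 33 matrix proteases and crosslinkers in MDA-MB-231, 22 were lower with IKVAV and 5 higher (median log2 -1.09, camera adjusted p = 8.23e-08). This list also passed when the correlation was estimated (adjusted p = 0.00535 with an estimated correlation). The stromelysin MMP10 (chromosome 11, 102641233 to 102651359) had 5 counts with IKVAV and 476 with GFOGER, and the plasminogen activator PLAT (chromosome 8, 42032236 to 42065194) fell from 1189 ± 274 to 148.4 ± 12.2 CPM. Hypoxia genes were lower in 19 of 28 cases and higher in 1 (median log2 -0.76, camera adjusted p = 2.15e-06, adjusted p = 0.544 with an estimated correlation), with the hexokinase HK2 at log2 -2.00. Immediate early genes were lower in 18 of 25 cases and higher in 1 (median log2 -0.58, camera adjusted p = 1.65e-06, adjusted p = 0.352 with an estimated correlation), such as JUNB and JUND (log2 -1.35 and -1.15). YAP and TEAD targets were lower in 15 of 24 cases (median log2 -0.47, camera adjusted p = 8.09e-05, adjusted p = 0.398 with an estimated correlation), such as the coagulation factor F3 and IGFBP3 (log2 -1.93 and -2.55). ER chaperones were lower in 13 of 20 cases and higher in 1 (median log2 -0.33, camera adjusted p = 0.000708, adjusted p = 0.524 with an estimated correlation), with HSPA5 at log2 -1.10. ATF4 stress genes were lower in 14 of 23 cases and higher in 1 (median log2 -0.52, camera adjusted p = 0.0139, adjusted p = 0.680 with an estimated correlation).

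Proliferation genes of MDA-MB-231 were higher with IKVAV in 30 of 40 cases (median log2 0.61, camera adjusted p = 1.67e-11, adjusted p = 0.216 with an estimated correlation), among them the replication genes CDC45 and MCM5 (log2 1.32 and 1.05). Oxidative phosphorylation genes were higher in 31 of 40 cases (median log2 0.37, camera adjusted p = 4.11e-08, adjusted p = 0.398 with an estimated correlation), with NDUFA1 at log2 0.95. Interferon response genes were higher in 21 of 34 cases and lower in 3 (median log2 0.68, camera adjusted p = 5.00e-06, adjusted p = 0.216 with an estimated correlation), with IFIT1 and IFIT3 at log2 1.27 and 0.96. Matrix receptors as a list did not pass (7 higher and 11 lower of 25, median log2 -0.17, camera adjusted p = 0.355, adjusted p = 0.544 with an estimated correlation). The laminin receptor subunit ITGA6 fell by log2 1.03 and ITGB1 by log2 0.36, its partner ITGB4 was higher (log2 0.77), the laminin chain LAMB3 was lower (log2 -1.87) and the collagen receptor DDR1 did not change (log2 0.10). Mesenchymal genes did not pass as a list (5 higher and 9 lower of 16, median log2 -0.70, camera adjusted p = 0.112, adjusted p = 0.398 with an estimated correlation). Adjusted over the list alone, the counts higher and lower became 33 and 0 for proliferation, 33 and 0 for oxidative phosphorylation, 2 and 19 for hypoxia, 23 and 3 for interferon response, 2 and 14 for ATF4 stress and 5 and 10 for mesenchymal genes, and the others stayed.

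The largest increases with IKVAV in MDA-MB-231, besides IQGAP2 and MUC5B, were the neutrophil surface gene CD177 (chromosome 19, 43857825 to 43867480, 91.9-fold, 316.8 ± 98.7 against 3.19 ± 1.90 CPM) and the transporter SLCO2B1 (8.03 ± 1.39 against 0.143 CPM). The largest decreases, besides MMP1 and MMP10, were the endothelial genes ESM1 (0 counts against 13.6 ± 6.31 CPM, at least 78.3-fold lower) and TIE1 (4 counts against 919). In all, 6849 of 15630 genes differed, 3293 higher and 3556 lower, of which 931 and 1291 at least 2-fold. In data simulated on these libraries with few genes changed, the fit recovered 58 of 67 genes changed 2-fold, and 9.6% of its calls were false.

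In T47D cells at D40, far fewer genes separated IKVAV from GFOGER, and hypoxia genes were higher with IKVAV. PFKFB4, a regulator of glycolysis (hg19 chromosome 3, 48555117 to 48594227), stood at 78.2 ± 12.8 CPM with IKVAV and 17.9 ± 1.48 CPM with GFOGER (SD, n = 3 each), 4.36-fold higher (log2 2.12, SE 0.18, edgeR adjusted p = 2.23e-05). KLF6, an immediate early transcription factor (chromosome 10, 3818188 to 3827473), stood at 347.2 ± 59.8 against 141.8 ± 5.16 CPM (log2 1.29, SE 0.12, edgeR adjusted p = 4.21e-05, n = 3 each). CDC20B (chromosome 5, 54408799 to 54469005), which lies in a locus of ciliated cells, was 5.31-fold higher at 13.5 ± 2.07 against 2.56 ± 2.26 CPM (log2 2.41, SE 0.40). None of ITGA2, ITGA6, ITGB1, ITGB4, DDR1 and LAMB3 changed (log2 0.09, 0.00, -0.10, -0.03, 0.15 and -0.20).

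Of 28 hypoxia genes in T47D, 25 were higher with IKVAV and 3 did not pass (median log2 0.93, camera adjusted p = 3.21e-37). The list also passed when the correlation was estimated (adjusted p = 0.0256 with an estimated correlation). HK2 was higher by log2 1.43 and VEGFA by log2 1.4. Immediate early genes were higher in 12 of 25 cases (median log2 0.50, camera adjusted p = 2.63e-14, adjusted p = 0.153 with an estimated correlation), with KLF10 at log2 0.96. Estrogen response genes were higher in 6 of 30 cases (median log2 0.21, camera adjusted p = 1.66e-07, adjusted p = 0.290 with an estimated correlation), with MYB at log2 0.79 and SERPINA1 at log2 0.54. Glycolysis genes were higher in 6 of 15 cases (median log2 0.28, camera adjusted p = 3.10e-05, adjusted p = 0.260 with an estimated correlation), with ALDOA at 2904 against 1904 CPM. ER chaperones were higher in 3 of 20 cases (median log2 0.15, camera adjusted p = 6.37e-05, adjusted p = 0.290 with an estimated correlation). Of 34 interferon response genes, 2 were lower (median log2 -0.55, camera adjusted p = 1.48e-09, adjusted p = 0.476 with an estimated correlation), namely SAMD9 and IFI35 (log2 -0.71 and -0.60). Of 40 proliferation genes, the cyclins CCNE1 and CCNE2 were lower (log2 -0.79 and -0.64, list median -0.26, camera adjusted p = 1.42e-07, adjusted p = 0.715 with an estimated correlation).

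Leaving out single libraries often lowered the counts of these T47D lists, while each median kept its sign. Hypoxia genes that were higher numbered 15 without GFOGER library 1. Immediate early genes numbered 4 without GFOGER library 1 or IKVAV library 3, 7 without GFOGER library 2 and 6 without IKVAV library 2. Estrogen response genes numbered 3 without GFOGER library 2 or 3 or IKVAV library 3 and 2 without IKVAV library 2, and glycolysis genes 3 without GFOGER library 1 or IKVAV library 3. ER chaperones numbered 0 without GFOGER library 1 or IKVAV library 2 or 3 and 1 without GFOGER library 2 or 3. Lower interferon genes numbered 0 or 1 without any library but IKVAV library 1, and lower proliferation genes 0 or 1 without any of the 6.

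Smaller shifts in T47D with IKVAV touched cell cycle exit genes (1 higher of 20, median log2 0.18, camera adjusted p = 0.00214, adjusted p = 0.260 with an estimated correlation), such as TOB1 at log2 0.47. T47D line markers were higher in 2 of 20 cases (median log2 0.17, camera adjusted p = 0.00400, adjusted p = 0.457 with an estimated correlation), and TGF-beta targets in 1 of 19 (median log2 0.12, camera adjusted p = 0.0312, adjusted p = 0.320 with an estimated correlation). Dormancy-associated genes were higher in 4 of 25 cases and lower in 1 (median log2 0.10, camera adjusted p = 0.02, adjusted p = 0.182 with an estimated correlation), and inflammatory genes lower in 1 of 25 (median log2 -0.22, camera adjusted p = 0.02, adjusted p = 0.799 with an estimated correlation). Of 18 antigen presentation genes, 0 passed (median log2 -0.11, camera adjusted p = 0.0296, adjusted p = 0.799 with an estimated correlation). The inflammatory median was 0.00 without GFOGER library 3, and inflammatory genes that were lower numbered 2 without IKVAV library 1 and 0 without any of the others. Without IKVAV library 1, 1 antigen presentation gene was lower, and the dormancy gene that was lower lost its call without any library but GFOGER library 3. Cell cycle exit genes that were higher numbered 2 without GFOGER library 3, and line markers 1 without any library but IKVAV library 1. TGF-beta targets numbered 0, 2 and 3 without GFOGER library 1, GFOGER library 3 or IKVAV library 1, with medians of 0.07, 0.05 and 0.25 without GFOGER library 1, 2 or 3. Adjusted over the list alone, the counts higher and lower became 27 and 0 for hypoxia, 15 and 0 for immediate early, 11 and 0 for estrogen response, 7 and 1 for glycolysis, 5 and 0 for ER chaperones, 0 and 14 for proliferation, 3 and 1 for cell cycle exit, 3 and 0 for line markers, 5 and 1 for dormancy, 0 and 2 for inflammatory genes and 6 and 1 for TGF-beta targets, and interferon and antigen presentation genes stayed. The other large increases were PPFIA4 (log2 2.06) and the cytokine signalling inhibitor SOCS3 (log2 1.81). The largest decreases were the chemokine CXCL10 (log2 -1.36), the xenobiotic enzyme CYP1A1 (chromosome 15, 75011883 to 75017877, log2 -1.19, 105.1 ± 3.74 against 238.5 ± 43.0 CPM), MUM1L1 (log2 -1.18) and the transporter SLC6A14 (log2 -1.11). CXCL10 and CCNE1 lost their calls without any 1 of the 6 libraries, IFI35 without any but IKVAV library 1, CYP1A1 and SAMD9 without GFOGER library 1 or 2 or IKVAV library 2 or 3, and CCNE2 without GFOGER library 1 or 2 or IKVAV library 1 or 3. With robust dispersion CYP1A1, SAMD9 and CCNE2 also lost theirs (edgeR adjusted p = 0.105, 0.0669 and 0.0549).

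In all, 601 of 15836 genes differed between the peptides in T47D, 372 higher and 229 lower with IKVAV, of which 78 and 15 at least 2-fold. With only the libraries compared the count was 1217 (678 higher and 539 lower), and with the DESeq2 Wald test 960 (473 higher and 487 lower). The count without GFOGER library 1, 2 or 3 was 150, 240 and 483, and without IKVAV library 1, 2 or 3 it was 378, 169 and 203, while PFKFB4 and KLF6 kept their calls. In data simulated on these libraries with few genes changed, the fit recovered 58 of 67 genes changed 2-fold, and 7.8% of its calls were false.

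The effect of the peptide differed between the lines for 5319 genes, 2724 with T47D minus MDA-MB-231 above 0 and 2595 below. Of the lists, 11 passed with camera and 1, the matrix proteases, also with an estimated correlation. Hypoxia genes, lower with IKVAV in MDA-MB-231 and higher in T47D, had 26 of 28 differences above 0 (median log2 1.73, camera adjusted p = 8.04e-19, adjusted p = 0.110 with an estimated correlation). Matrix proteases and crosslinkers had 15 of 33 above 0 and 2 below (median log2 0.96, camera adjusted p = 2.18e-05, adjusted p = 0.0147 with an estimated correlation). Proliferation genes had 31 of 40 below 0 (median log2 -0.83, camera adjusted p = 5.61e-15, adjusted p = 0.352 with an estimated correlation). Hypoxia genes and proteases above 0 numbered 27 and 18, and proliferation genes below 0 numbered 34, when adjusted over the list alone. The log2 fold changes of the lines correlated at -0.056 (Pearson) and -0.090 (Spearman), and of 305 genes that differed in both lines, 101 (33.1%) went the same way.

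D40 was also compared with D3 in the IKVAV gel, where each line has 1 D3 library whose spread is assumed to be that of the other groups, and where the 2 times lie in different library sets. In MDA-MB-231, LCN2 stood at 289.1 ± 80.4 CPM at D40 (SD, n = 3) and 1.02 CPM in the D3 library (log2 8.12, SE 0.58, edgeR adjusted p = 3.32e-09), and IL1B at 47.4 ± 19.5 against 1.99 CPM (log2 4.56, SE 0.57). MKI67 was higher at D40, at 1276 ± 140.0 against 700.3 CPM (log2 0.85, SE 0.17, edgeR adjusted p = 0.00103, n = 3 and 1). Inflammatory genes rose in 27 of 30 cases (median log2 3.29, camera adjusted p = 3.15e-21, adjusted p = 0.0803 with an estimated correlation) and hypoxia genes in 17 of 28 (median log2 0.70, camera adjusted p = 3.78e-07, adjusted p = 0.417 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 25 cases (median log2 -0.73, camera adjusted p = 1.66e-09, adjusted p = 0.0803 with an estimated correlation). Proliferation genes did not pass (2 risen and 2 fallen of 40, median log2 0.01, camera adjusted p = 0.738, adjusted p = 0.904 with an estimated correlation). Cholesterol genes that fell numbered 19, and proliferation genes 1, when adjusted over the list alone, and the other counts stayed. In all, 3098 genes differed, 1416 up and 1682 down.

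In T47D over the same step with IKVAV, NDRG1 stood at 212.5 ± 50.3 CPM at D40 (SD, n = 3) and 7.61 CPM in the D3 library (log2 4.69, SE 0.38, edgeR adjusted p = 3.47e-08), and IFIT2 at 27.9 against 2.29 CPM (log2 3.49, SE 0.46). MKI67 was lower, at 383.2 ± 34.4 against 518 CPM (log2 -0.55, SE 0.16). Proliferation genes fell in 39 of 40 cases (median log2 -1.12, camera adjusted p = 1.08e-14, adjusted p = 0.302 with an estimated correlation), and all 40 oxidative phosphorylation genes fell (median log2 -0.92, camera adjusted p = 8.31e-17, adjusted p = 0.265 with an estimated correlation). Hypoxia genes rose in 25 of 28 cases (median log2 1.69, camera adjusted p = 2.78e-13, adjusted p = 0.192 with an estimated correlation), and dormancy-associated genes in 16 of 25 with 2 fallen (median log2 1.04, camera adjusted p = 0.000149, adjusted p = 0.0579 with an estimated correlation). Hypoxia and dormancy genes that rose numbered 26 and 17 when adjusted over the list alone, and the other counts stayed. In all, 7488 genes differed, 3455 up and 4033 down. RPL7A and EEF1A1, which have copies, were lower at D40 in both lines (log2 -2.95 and -4.60 in MDA-MB-231, -2.91 and -4.66 in T47D).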

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

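The test of whether gel acts alike on both lines, that of the shift in ER chaperones and the test for cells of the other line were chosen after the results were seen, as was the number of regroupings between lines, which was raised to 60. Groups of 3 are too small for a test of single outlying samples, so the changes singled out are those that differ between the lines. Values are log2 of the T47D change minus the MDA-MB-231 change, from the edgeR fit of both lines. Where a group holds no counts the value has no upper bound and only its sign counts.

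Over time in the 10 wt% gel, the change differed for 9416 genes. Differences above 0 were largest for CDC20B (8.85, SE 2.45, adjusted p = 0.00319), APLN (8.52, SE 0.72), ROBO2 (7.79, SE 1.82) and NGFR (7.78, SE 0.92). In T47D, CDC20B went from 0.501 to 12.5 CPM and ROBO2 from 0.849 to 17.6 CPM, while MDA-MB-231 had almost no counts of either. The vessel peptide APLN rose in T47D from 0.251 to 8.48 CPM and fell in MDA-MB-231 from 5.56 to 0.368 CPM, and the receptor NGFR went from 0.408 to 1.83 and from 10.5 to 0.148 CPM. Differences below 0 were largest for KRT4 (-9.86), TREM1 (-8.74), IL1B (-7.56) and MMP1 (-6.72, SE 0.42), each of which rose in MDA-MB-231 and stayed near or under 2 CPM in T47D. The calls for CDC20B and TREM1 were lost without 1 library (adjusted p = 0.0756 and 0.0733). Heat shock genes had a median difference of -1.3 (13 of 15 below 0, camera adjusted p = 2.32e-07, adjusted p = 0.207 with an estimated correlation) and interferon response genes of 3.14 (camera adjusted p = 4.98e-07, adjusted p = 0.461 with an estimated correlation).

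Between the 10 wt% and standard gels, the difference was itself different for 8728 genes. It was largest above 0 for SLITRK1 (8.53, SE 1.25), the growth factor FGF5 (8.21, SE 0.51), APOBEC3D (7.95, SE 0.84) and the BMP regulator BMPER (7.94, SE 0.57). FGF5 stood at 3.80 against 0.0342 CPM in T47D and 14.4 against 54.3 CPM in MDA-MB-231, and BMPER at 2.75 against 2.18 and 0.0421 against 10.5 CPM. It was largest below 0 for GSPT2 (-7.66), which resembles a parent gene, ARL11 (-6.76), DSCR6 (-6.70) and the kinase HUNK (-6.65). HUNK stood at 35.3 against 53.3 CPM in T47D and 1.31 against 0.0152 CPM in MDA-MB-231.

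Between IKVAV and GFOGER, the effect differed for 5319 genes. It was largest above 0 for ESM1 (11.04), C21orf7 (7.64), MMP1 (6.99, SE 0.30) and FUT3 (6.74), and below 0 for SLCO2B1 (-6.38), CD177 (-6.25), IQGAP2 (-5.67) and CH25H (-5.55). MMP1 stood at 5.76 against 6.07 CPM in T47D and 101.9 against 12510 CPM in MDA-MB-231, and IQGAP2 at 1.69 against 1.31 and 163.0 against 2.24 CPM. The calls for ESM1 (adjusted p up to 1), C21orf7 (0.0892), SLCO2B1 (up to 0.975) and CH25H (0.215) were lost when a single T47D library was left out. That for ESM1 was also lost with only the libraries compared (0.0671) and that for SLCO2B1 with the replicate number as a block (0.0604). T47D has few counts of these genes. Of 11 lists that passed with camera, 5 had also passed in opposite directions in the lines: proliferation (median -0.83), hypoxia (1.73), ER chaperones (0.41), interferon response (-1.16) and immediate early genes (1.22). In the last 3, 15 of 20 were above 0, 24 of 34 below and 17 of 25 above (camera adjusted p = 9.06e-07, 8.09e-09 and 1.23e-11). With an estimated correlation none of the 5 passed (adjusted p = 0.352, 0.110, 0.187, 0.579 and 0.107), while matrix proteases and crosslinkers did (median 0.96, adjusted p = 0.0147).

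Libraries were regrouped, in all 10 ways within a line and at random between lines, to see how often a false grouping gives as many calls. In each comparison within a line, 1 of 10 regroupings, the real one, gave as many and the highest other gave 0, but 10 are too few to bring the share under 0.05. Between lines, 1 of 60 did so for time (highest other 9070), for peptide (4902) and for the lines themselves (4076). These highest others came from regroupings that keep a real pair of groups whole. Without such a pair the highest was 0 for time, 2 for peptide and 0 for the lines. A regrouping that mixes real groups puts their differences into the spread, so few calls are built in. These shares therefore do not test whether the real calls arose by chance. For the gel, 4 of 60 gave as many genes as the real grouping, up to 10482, so this count does not exclude a random grouping. Of these 4, 1 is the real grouping and 3 keep the 2 gels of 1 line whole, and no regrouping without such a pair gave any call.

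The first pattern is the gel comparison, whose libraries lie in 2 sets: if reads shared with copies were counted differently in the sets, genes with copies should change 2-fold over 1.5 times as often as other genes in both lines. The share was 2.06 times that of other genes in T47D (19.5 against 9.5%) but 1.17 times in MDA-MB-231 (41.5 against 35.5%), which misses the margin. In the other comparison between the sets, D40 with D3 in IKVAV, the ratio was 2.06 in MDA-MB-231 and 1.70 in T47D, and within a set it was 0.84, 0.41, 0.59 and 0.40. The margin was missed where 35.5% of other genes changed too, against 9.3 to 16.7% in the other 3 comparisons between sets, so sharing of reads stays open for genes with copies. Without pseudogenes and genes with copies, 9697 genes in MDA-MB-231 and 5772 in T47D still differed, by gel or by library set, which cannot be told apart, although a set effect alike in both lines would not give the median difference of 1.4 in proliferation genes.

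The second pattern is the fall of proliferation genes and the rise of ER chaperones in MDA-MB-231 at D40 in the 10 wt% gel. If a few abundant genes had pushed proliferation genes down, the median without them, scaled by totals in place of TMM, should lie above -1.3. That limit was set beforehand. The median was -3.01, but removal moved it by only 0.06, and the rest of the step from -2.64 came from the scaling. Under totals, removal shifts all remaining genes alike, and by little for genes that hold so small a share of counts. The limit could thus not be reached, and the values show only that the abundant genes account for 0.06 of the fall. For ER chaperones the limit was a median below 0.8 (it was 1.07), which decides nothing, since abundant genes that gain share lower all others. Taking them out raised the median by 0.06 on the same 18 members under totals. Their gain in share fixed that sign beforehand, so this gain did not make the rise. Scaling by totals with no gene removed gave -3.07 and 1.01, against -2.64 and 1.44 on those members with TMM, so the size of both changes depends on the scaling. Over all genes the change hardly followed GC content or gene length (Spearman 0.01 and 0.03), so there was little trend to remove. After removing it the medians were -2.56 and 1.60, still beyond -1.3 and 0.8, so these trends are not the whole cause. Growth of the cells was not measured here.

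The third pattern is that hypoxia genes were lower with IKVAV in MDA-MB-231 and higher in T47D. With an estimated correlation the T47D list passed, but neither the MDA-MB-231 list nor the difference between the lines did. Leaving out each library in turn, the median closest to 0 was -0.63 in MDA-MB-231 and 0.84 in T47D, so no single library carries the pattern. The highest share of the other line's cells by line markers was 3.24%, which is too low to turn the direction. The opposite directions could arise if oxygen use or cell density in the gels differed, which counts cannot show.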

How the results depend on the processing

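The gene sets without copies, without the most abundant genes and the lists without 2 libraries were chosen after results were seen, and all other alternatives were set before. With a 2-fold minimum, counts for time, gel and peptide became 6613, 5862 and 2222 in MDA-MB-231 and 2095, 1882 and 93 in T47D. The split of the gel comparison between lines, 5292 above 0 and 3436 below, became 3977 and 3888 with only the libraries compared. With the 2-fold minimum the counts between lines became 5755, 4817 and 2115 for time, gel and peptide, and 8212 for the lines themselves. Limma-voom, robust dispersion and the stricter filter were run for the 6 main comparisons only. Under the alternatives run other than the 2-fold minimum, gene counts stayed within 1.5 times the main value, apart from the peptide comparison of T47D. There, 601 genes became 960 with the DESeq2 Wald test, in which the split turned from 372 higher and 229 lower to 473 higher and 487 lower. It became 1217 with only the libraries compared, and 150, 240 and 483 without GFOGER library 1, 2 or 3 and 378, 169 and 203 without IKVAV library 1, 2 or 3. The cause of these moves was not tested. Of 1613 values for named genes under other methods, 1607 kept their call and 6 lost it, and of 1482 values with a library left out, 1430 kept it, 52 lost it and 0 turned direction. Over the 6 main comparisons, 71 list tests passed with camera, 2 with an estimated correlation and 118 with fry, which does not compare a list with other genes. The list results thus suggest direction and size of shift in these libraries more than a rank above other genes. With single libraries left out, which was run only for lists that had passed in the main comparisons, no list median of MDA-MB-231 moved by over 1.5 times. Over time in T47D those that did were histones (-0.93 to -1.44), inflammatory (0.65 to 0.41) and immediate early genes (0.66 to 0.35) without the third D40 library, interferon (0.79 to 0.40) without the second and fatty acid synthesis (-0.32 to -0.51) without the first. Between gels they were inflammatory (-1.18 to -1.92) and oxidative phosphorylation genes (0.16 to 0.26) without the third, interferon (-0.77 to -1.23) without the second and oxidative phosphorylation (to 0.09) without the first. With peptide they were dormancy, antigen presentation, inflammatory and TGF-beta lists, all with main medians within 0.22 of 0. DESeq2 size factors moved the median of all genes from 0.146 to 0.088 between lines for time and from 0.223 to 0.135 for gel, and turned the sign of no list that had passed. Depth limits genes near 1 CPM, where most of the 4-fold changes missed in simulated data lay.

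Replicate numbers gave no sign of pairing the libraries. The correlation of residuals between libraries with the same number had a median of 0.006 in MDA-MB-231 (-0.088 to 0.165) and -0.002 in T47D (-0.050 to 0.092). Between libraries with different numbers the medians were 0.009 and 0.001. With the number as a block, counts for time, gel and peptide were 10935, 10613 and 6695 in MDA-MB-231, 8306, 6634 and 675 in T47D, and 9412, 8713 and 5370 between lines. The block changed no list call (71).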

Other observations

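The list of motile cilium genes was drawn up after CDC20B was seen to be higher with IKVAV in T47D, so its test was chosen after the result was seen. CDC20B lies beside CCNO in a locus active in cells with many cilia, which led to the hypothesis that genes of motile cilia are higher with IKVAV in T47D. Of 53 genes listed without CDC20B, 38 could be tested. Their median log2 fold change was 0.45, with 29 above 0, 4 called higher and 1 lower, and camera gave p = 2.29e-05 (p = 0.0728 with an estimated correlation). CCDC103 (log2 0.72), CCDC151 (0.75), CCNO (0.58) and NME5 (1.27) were higher and MNS1 (-0.44) was lower. CCNO lies in the locus that prompted the list, and the libraries are those in which CDC20B was seen, so its call is not separate support. Most levels were low, with CCNO at 17.9 against 11.9 CPM and NME5 at 2.00 against 0.822 CPM. Over time in the 10 wt% gel of T47D, 18 of the 38 rose and 4 fell (median log2 0.81, camera p = 0.00549, p = 0.215 with an estimated correlation). Between the 10 wt% and standard gels, 7 were higher and 5 lower, and the list did not pass (median log2 0.28, camera p = 0.296, p = 0.624 with an estimated correlation). The shift with IKVAV met its prediction with the preset correlation alone, rests on few called genes, and may also reflect the hypoxia and immediate early shift of the same libraries.

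Among 2 libraries that diverged from their group was the third of MDA-MB-231 in standard GFOGER at D40. The chi-square per degree of freedom of counts between 2 replicates was 62.52 and 55.17 with it and 12.1 without it. Leaving it out raised the count for the peptide to 7444. The list counts kept their direction (21 matrix proteases lower and 23 hypoxia genes lower). Medians shrank for ER chaperones (-0.33 to -0.22, 13 to 10 lower) and YAP and TEAD targets (-0.47 to -0.32, 15 to 12 lower). That of ATF4 stress genes went from -0.52 to -0.38 (14 to 12 lower, 1 to 3 higher). Hypoxia and immediate early genes moved the other way (-0.76 to -0.91 and -0.58 to -0.64). In the gel comparison of MDA-MB-231, leaving it out moved some medians away from 0 (heat shock 1.11 to 1.41) and others towards 0 (interferon response -1.1 to -0.91). The third of T47D in the 10 wt% gel at D40 had more MALAT1 than the other 2, and without it 24 interferon genes rose over time instead of 17 (median 0.97 instead of 0.79), while without the second library 12 did (median 0.40).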
